A study of Homo sapiens with 9 samples.

How the data were processed

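RNA from MCF7 cells, extracted with Trizol per the labels, was hybridised to Affymetrix arrays in 3 groups of 3: luciferase shRNA, NIK shRNA and NIK overexpression from an expression vector. The values are log2 intensities per probe set as deposited by the authors; the submitters' processing notes name RMA, oligo and limma, without versions or roles. The array columns had near-equal quartiles, from 6.19 to 6.22 for the lower one, and no centring per gene was seen. The genome build is not given in the sources used here. Probe sets are at the exon level, which was found from the files and not foreseen when the design was fixed.

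The table held 65528 probe sets. Gene symbols came from the platform's annotation: 54805 probe sets had 1 symbol, 2142 had several and 8581 had none. Symbols were updated through the gene table of assembly GRCh38.p14, which holds 4689 of the 4713 genes and changed the symbol of 591. No coordinates of that table were used, because the build of the files is not given. The genes lie on chromosomes 1 (1880 genes), 10 (691), 11 (1239) and 12 (850), and 53 lie elsewhere or were not placed, so most of the genome was not analysed here. A gene had a median of 10 probe sets and at most 107, and 373 genes had 1. Probe sets with all 9 values equal to those of another numbered 1211. Unnamed probe sets, which would include any control probe sets, were left out of the fit, and a gene was never named from a probe set with several symbols.

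Differences were tested with limma 3.58.1 (lmFit, contrasts and eBayes) in R 4.3.3, on all 9 arrays in 1 fit with group means only, which leaves 6 residual degrees of freedom. All named probe sets entered eBayes. Each gene was represented by its single-symbol probe set with the highest mean over the 9 arrays, and Benjamini-Hochberg adjustment ran over the 4713 genes. A gene was called at adjusted p 0.05. An F-test asked for any difference among the 3 groups. Intervals are at the 95% level, and differences are log2 values of the first group minus the second. The number of arrays limits the precision, and brightness over background was not given by the files.

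Choices fixed before the data were examined were the groups, the tests, 27 gene lists, the alternatives and the rule for named genes. The rule takes MAP3K14; for each comparison the 10 largest rises and falls that pass with arrays that do not overlap, or, where none pass, the 5 smallest p in each direction; NFKB2, RELB, NFKBIA, BIRC3, TNFAIP3, CXCL8 and ESR1 in every comparison; and up to 4 members with the smallest p of each list described. Lists were described with 3 members each where they belong to NF-kB signalling or had an unadjusted camera p under 0.05, a restriction made after the data were seen. TCN1 on the mean over probe sets was named after its values were seen. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 24 lists that had at least 3 measured members, a minimum chosen after the data were seen; camera with an estimated correlation (statmod 1.5.0) and fry were alternatives. Antigen presentation genes and mitochondrially encoded transcripts had 0 measured members and replication-dependent histones had 2, so these 3 lists were not tested; the 2 histone genes had a median log2 difference of −0.18 for NIK overexpression against control, −0.04 for NIK shRNA against control and −0.14 between the 2 arms.

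The fit was tested on simulated data with 200 genes changed among 4713. For NIK overexpression against control it recovered 38% of genes changed by 0.5 on the log2 scale, 82% at 1, 92% at 1.5 and 98% at 2. For NIK shRNA against control the shares were 42%, 88%, 92% and 100%, and for NIK overexpression against NIK shRNA they were 48%, 86%, 96% and 98%. Between 1 and 3 unchanged genes were called in a comparison. The simulated noise was drawn independently for each probe set, with no difference shared across an array. The shares also depend on 200 genes being changed. In the deposited data 7, 10 and 6 genes differed by more than 1 on the log2 scale in these 3 comparisons, and 0 were called. The simulated shares are therefore not the chance of finding such a change in these arrays.

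The fit was also varied, as fixed in advance, by taking the replicate number as a block, the 6 compared arrays alone, a further quantile normalization, centring each array on its median, leaving out probe sets below the median brightness, eBayes with trend and robust, array weights, adjustment over every probe set, leaving out each array, a minimum change of 1.5-fold and an adjusted p of 0.01. Variations added after the data were seen were the mean over all probe sets of a gene, the array contrast (mean of the brightest 20% of genes minus that of the dimmest 20%) as a covariate, and leaving out both arrays at the ends of the first principal component (control 2 and NIK overexpression 2). To see what shared controls give with no effect, residuals of the 9 arrays were permuted and given random signs in 100 draws. Plots were drawn with matplotlib 3.10.9.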

Results

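Gene expression was measured in MCF7 cells, an established human breast cancer line of the luminal, oestrogen receptor-positive kind, after transient lipid-mediated transfection with 1 of 3 constructs. The control cells received a short hairpin RNA (shRNA) against luciferase, a gene that human cells lack. The depleted cells received an shRNA against NIK, and the overexpressing cells received a vector with the full NIK reading frame. NIK, encoded by MAP3K14, is the kinase that starts the noncanonical branch of NF-kB signalling by way of the kinase CHUK and the precursor encoded by NFKB2. Per the labels, cells were analysed for NIK expression 48 h after transfection. Each group had 3 arrays, 9 in all, and the deposited values were log2 RMA values per probe set, with array medians between 7.87 and 7.92. The labels give triplicates but do not say that they were separate cultures, so p-values measure only the spread between these arrays. Correlations across probe sets ran from 0.968 to 0.978 between arrays of 1 group and from 0.965 to 0.977 between arrays of different groups. The number of arrays limits the precision: the median 95% interval of a gene's log2 difference reached 0.31 to either side, a factor of 1.24.

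The values held here covered 4713 named genes, of which 4660 lie on chromosomes 1, 10, 11 and 12 in the reference gene table of assembly GRCh38.p14. MAP3K14 was not analysed here, so the level of the targeted transcript gives no check of the array labels. Nor was it seen whether the constructs lowered or raised NIK in these arrays. Depletion and overexpression therefore name the construct that the cells received. A missing response cannot be told apart from a construct without effect. RELB, NFKBIA, TNFAIP3, CXCL8 and ESR1, fixed in advance as genes to name, were also not analysed here. NFKB2 and BIRC3 were measured.

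NIK overexpression was first set against the luciferase control, which asks what differs in MCF7 cells that carry the NIK vector. The genes that stood highest over control with the smallest p were INHBE, a subunit of the activin and inhibin family, and DUSP6, a phosphatase that inactivates ERK and is itself induced by ERK signalling. INHBE lay at 8.98 ± 0.099 (SD, n = 3) with NIK overexpression and 7.96 ± 0.10 (SD, n = 3) in control, a 2.03-fold difference on the brightest of its probe sets. INHBE's other 2 probe sets were higher by 0.12 and 0.07 on the log2 scale, with arrays that overlapped the control. DUSP6 lay at 8.58 ± 0.23 (SD, n = 3) and 7.49 ± 0.18 (SD, n = 3), a 2.14-fold difference. TXNIP, which encodes the thioredoxin-interacting protein, stood 1.47-fold higher, ERRFI1, a feedback inhibitor of the EGF receptor, 1.45-fold, and MYEOV 1.85-fold. None of these passed limma's test with Benjamini-Hochberg adjustment over 4713 genes: adjusted p was 0.103 for INHBE (log2 difference 1.02 ± 0.12 SE), 0.160 for DUSP6 (1.10 ± 0.15 SE) and 0.540 for TXNIP (0.56 ± 0.10 SE), ERRFI1 (0.54 ± 0.11 SE) and MYEOV (0.89 ± 0.18 SE). In each of the 5 genes all 3 overexpression arrays lay above all 3 control arrays. The genes were picked for the smallest p on these same arrays, so this adds no separate support.

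On the lower side, PCDH15, a protocadherin, stood 3.89-fold lower on its brightest probe set (log2 difference −1.96 ± 0.29 SE, limma adjusted p 0.205). That difference was not shared by the gene's other probe sets: 16 of its 34 probe sets were higher, and the mean over them differed by −0.09 ± 0.10 (SE). UBQLNL (−0.93 ± 0.17 SE) and CATSPERE (−0.59 ± 0.12 SE), which encodes a subunit of the sperm calcium channel complex, likewise had 2 of 4 and 9 of 21 probe sets higher. AVIL, the actin-binding protein advillin, differed by −0.59 ± 0.12 (SE) with 18 of 20 probe sets lower, and SHCBP1L by −0.61 ± 0.13 (SE) with 12 of 14 lower. Limma's adjusted p was 0.540 for UBQLNL and CATSPERE and 0.565 for AVIL and SHCBP1L.

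Because most genes had several probe sets (median 10), the comparison was also made on the mean over all probe sets of a gene, a choice made after the data were seen. On that mean 3 genes passed limma's test, all higher with NIK overexpression. TCN1, which encodes a secreted vitamin B12-binding protein, stood at 8.16 ± 0.047 (SD, n = 3) with NIK overexpression, 6.998 ± 0.32 (SD, n = 3) in control and 7.06 ± 0.070 (SD, n = 3) with NIK shRNA. Its log2 difference from control was 1.17 ± 0.13 (SE, limma adjusted p 0.0129), and all 10 of its probe sets were higher, by 0.68 to 1.82. The smallest difference was that of the brightest probe set. The largest was that of a dim probe set at 5.15 ± 0.87 (SD, n = 3) in control, below the lower quartile of the arrays. The next largest, 1.66, was that of a probe set at 7.78 ± 0.63 (SD, n = 3) in control. TXNIP rose by 0.69 ± 0.094 on the log2 scale (SE, limma adjusted p 0.0407), with 10 of 10 probe sets higher, and DUSP6 rose by 0.75 ± 0.11 (SE, limma adjusted p 0.0451), with 6 of 7 higher. These 3 calls were sensitive to the arrays used: without 1 array between 0 and 3 genes passed, and 0 passed without control 1, NIK overexpression 1, NIK overexpression 2 or NIK overexpression 3. INHBE, called by neither summary, differed by 0.40 ± 0.099 (SE) on the mean, with limma adjusted p 0.175.

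**Figure D1:**
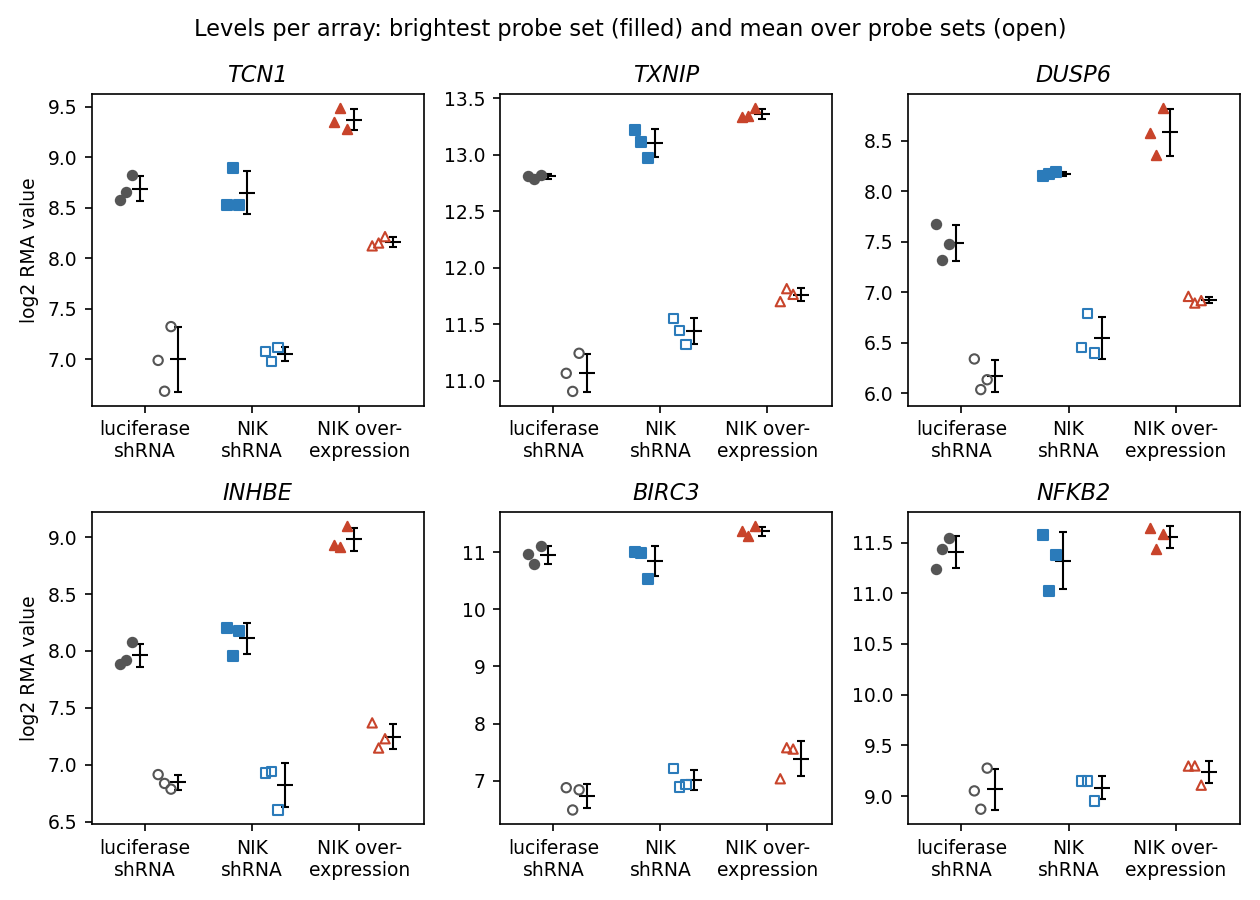
Log2 RMA values of TCN1, TXNIP, DUSP6, INHBE, BIRC3 and NFKB2 on each array by group, for the brightest probe set (filled) and the mean over the gene's probe sets (open); black bars give the mean and SD of 3 arrays, and the vertical axes do not start at 0. For the TCN1 mean, the overexpression arrays lay between 8.12 and 8.22 and the control arrays between 6.68 and 7.32.

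**Figure D2:**
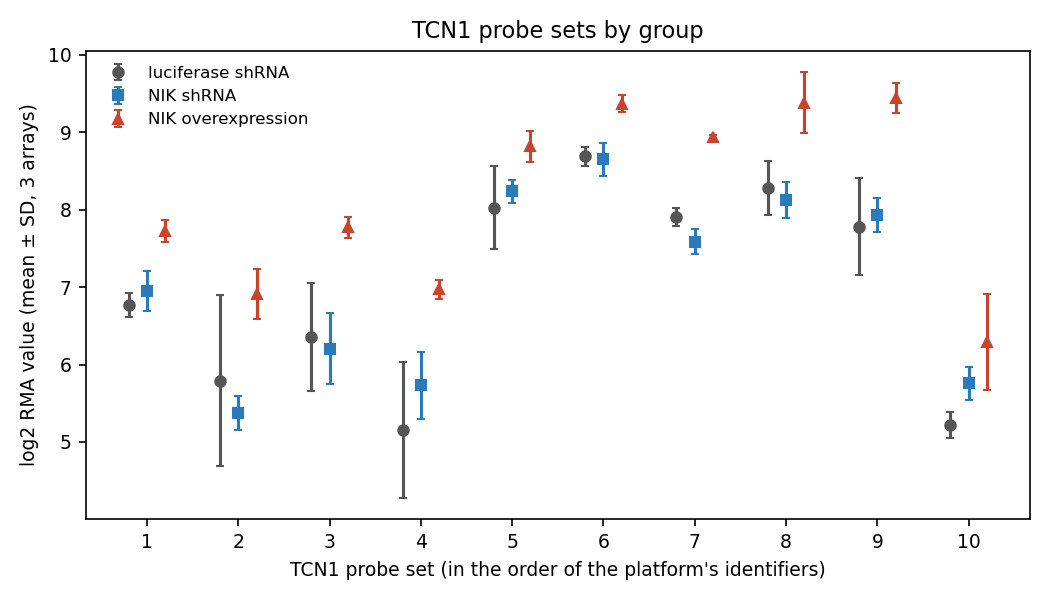
Log2 RMA value (mean and SD of 3 arrays) of each of the 10 TCN1 probe sets in the luciferase shRNA, NIK shRNA and NIK overexpression groups. All 10 had a higher mean with NIK overexpression than in control, and in 9 of them all overexpression arrays lay above all control arrays.

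None of the measured NF-kB genes passed limma's test. BIRC3, an inhibitor of apoptosis and an NF-kB target, stood 1.33-fold higher with NIK overexpression (log2 difference 0.41 ± 0.15 SE, 95% interval 0.06 to 0.77, limma adjusted p 0.939). All 10 BIRC3 probe sets were higher, by 0.41 (the brightest) to 1.04 with a median of 0.63, and their mean differed by 0.65 ± 0.16 (SE, limma adjusted p 0.172). NFKB2 differed by 0.14 ± 0.16 (SE, 95% interval −0.23 to 0.51, limma adjusted p 0.947). Of 8 measured components of the noncanonical pathway 4 were higher and 4 lower, with a median of 0.03, and camera's adjusted p was 0.449. Among them LTBR, the lymphotoxin beta receptor, differed by −0.17 ± 0.14 (SE) and CHUK by 0.11 ± 0.10 (SE). Of 4 canonical components and feedback targets 2 were higher and 2 lower (median 0.03, camera adjusted p 0.519), with RELA at −0.09 ± 0.11 (SE). The 3 measured chemokines and cytokines were all lower (median −0.10, camera adjusted p 0.449): CXCL12 by −0.22 ± 0.14 (SE), CSF1 by −0.10 ± 0.12 (SE) and IL23A by −0.06 ± 0.18 (SE). Adjusted over the list alone, 0 genes passed in any of these 3 lists.

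Of 24 gene lists tested, 1 was called. The list of immediate early genes, many of which respond within minutes to growth factors and stress, also holds DUSP6, which is induced by ERK signalling. The immediate early genes were higher in 8 of 10 measured members with a median of 0.17 (camera adjusted p 0.00132). That median lay between 0.14 (without control 2) and 0.28 (without NIK overexpression 1) when single arrays were left out. The call was lost with an estimated correlation between genes (adjusted p = 0.178), and fry gave an adjusted p of 0.0318. DUSP6 was the 1 member that passed when adjusted over the list alone, against 0 over all genes. It stood beside the transcription factors JUN (0.40 ± 0.14 SE) and KLF6 (0.41 ± 0.14 SE), neither of which passed. A further 5 lists had an unadjusted camera p under 0.05 but were not called, with adjusted p from 0.0803 to 0.139. Apoptosis regulators were higher in 4 of 5 members (median 0.18, camera adjusted p 0.0803), with CASP9 at 0.72 ± 0.31 (SE) and MCL1 at 0.18 ± 0.087 (SE), against 0.11 and 0.04 on the mean over their probe sets. Heat shock genes were higher in 7 of 8 (median 0.11, camera adjusted p 0.0803), with CHORDC1 at 0.38 ± 0.13 (SE), DNAJB4 at 0.20 ± 0.13 (SE) and HSPA6 at 0.20 ± 0.17 (SE), the last turning to −0.03 on the mean over its probe sets. Genes of the unfolded protein response and ATF4 were higher in 5 of 6 (median 0.11, camera adjusted p 0.0985), with DDIT4 at 0.41 ± 0.17 (SE), SESN2 at 0.26 ± 0.15 (SE) and HSP90B1 at 0.07 ± 0.090 (SE). Glycolysis and hypoxia genes were higher in 8 of 10 (median 0.05, camera adjusted p 0.139): PFKFB3 differed by 0.28 ± 0.11 (SE) and BNIP3 by 0.27 ± 0.11 (SE), while ADM differed by −0.46 ± 0.18 (SE). Cell cycle genes were lower in 4 of 4 (median −0.17, camera adjusted p 0.0803), with the mitotic activator CDC20 at −0.30 ± 0.14 (SE), the spindle kinesin KIF11 at −0.19 ± 0.12 (SE) and CENPF at −0.14 ± 0.12 (SE).

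The other 15 lists had adjusted p from 0.449 to 0.922 in camera. Higher members numbered 4 of 6 stemness factors (median 0.03), 3 of 5 Notch pathway genes (0.0098), 3 of 6 genes of epithelial-mesenchymal transition (0.01), 5 of 9 p53 targets (0.01), 3 of 7 cholesterol biosynthesis genes (−0.0028), 7 of 11 small nucleolar RNAs (0.06) and 4 of 5 fibroblast markers (0.13). Lower members numbered 7 of 9 oestrogen receptor targets (median −0.08), 3 of 3 DNA replication genes (−0.07), 9 of 13 interferon-stimulated genes (−0.01), 3 of 4 ribosomal protein genes (−0.03), 3 of 5 luminal markers (−0.05), 5 of 8 basal markers (−0.15), 5 of 8 immune cell markers (−0.08) and 3 of 4 endothelial markers (−0.26). Among the small nucleolar RNAs, SNORD14E (−0.39 ± 0.095 SE, limma adjusted p 0.752) was lower when adjusted over the list alone. Median, mean and camera's direction differed in sign for the Notch, cholesterol, ribosomal protein and immune lists. On the mean over probe sets the median turned sign for oestrogen receptor targets (0.02), basal markers (0.03), fibroblast markers (−0.0055) and ribosomal protein genes (0.07). It also turned for the Notch pathway (−0.06) and cholesterol biosynthesis genes (0.07). By limma on the brightest probe sets 0 genes were called at adjusted p 0.05. An unadjusted p under 0.05 was reached by 235 genes, or 4.99% (110 higher, 125 lower). Evenly spread p-values would give 235.65, while 2.48% of unchanged genes reached such a p in the simulated data. The number was 561 on the mean over probe sets and 384 with trend and robust in limma's eBayes. With the array contrast as a covariate it was 125 on the brightest probe sets and 344 on the mean over probe sets. That contrast averaged 5.24 with NIK overexpression and 5.17 in control, so the number was not separated from it. Genes whose 3 arrays of 1 group all lay above or below those of the other made up 12.9%, where chance alone gives 10%. The array contrast was not removed from this share, and its excess over 10% was not tested. The 2 arms differ in the vector as well as in NIK, because the control carried an shRNA and no empty expression vector was among the samples.

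**Figure D3:**
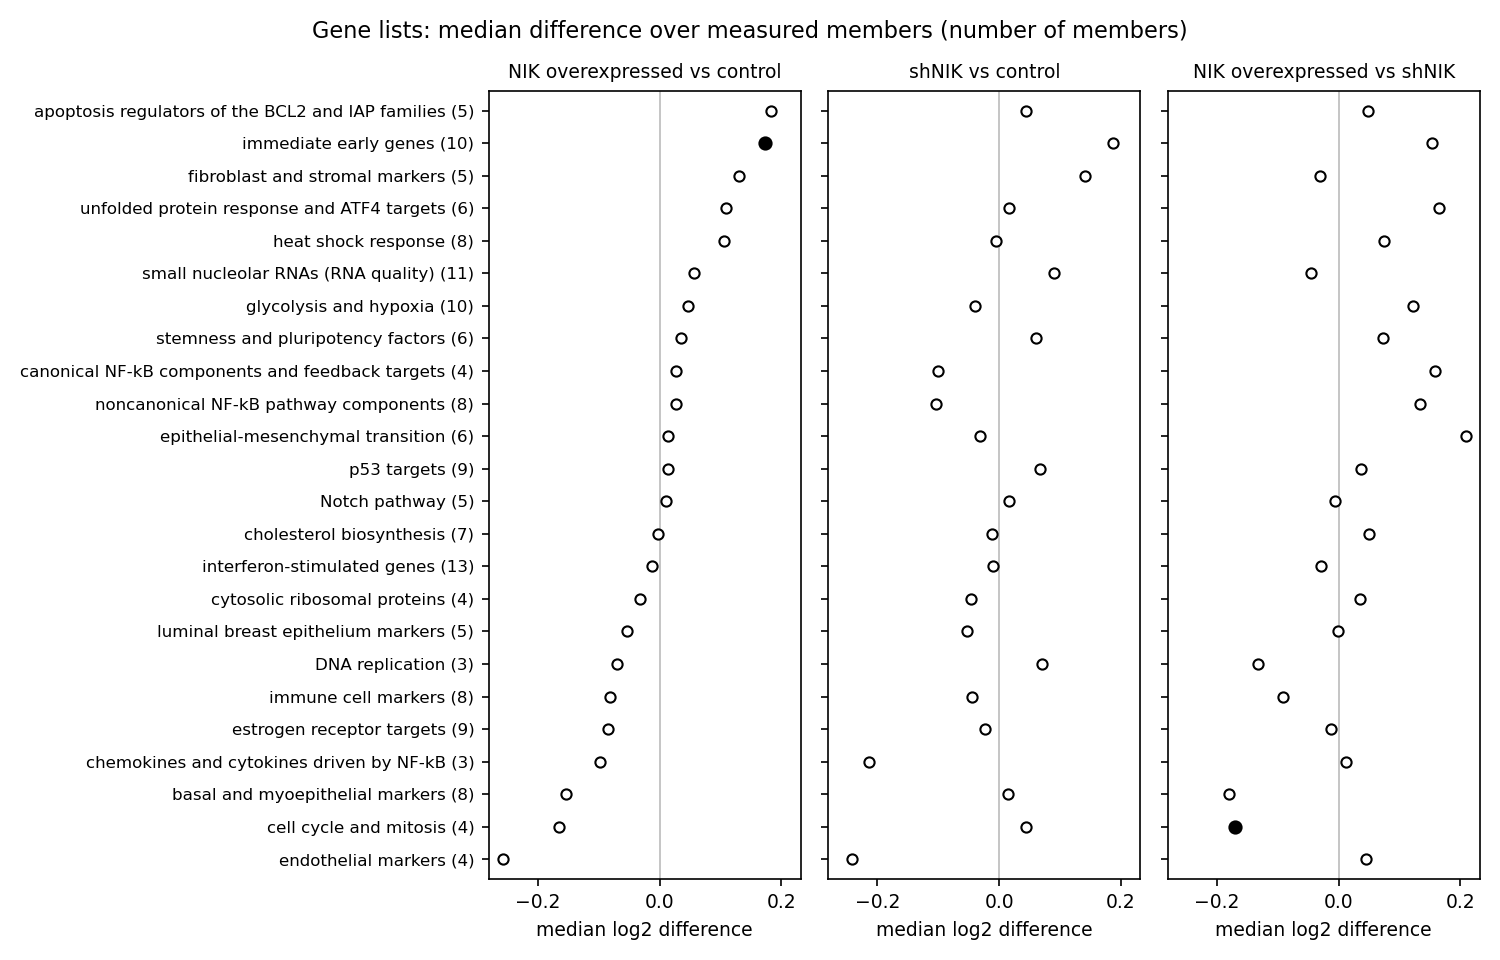
Median log2 difference over the measured members of each of 24 gene lists in the 3 comparisons, with the number of members in parentheses; filled circles mark lists called by camera with the preset correlation and open circles the others. Immediate early genes (NIK overexpression against control) and cell cycle genes (NIK overexpression against NIK shRNA) were the 2 called, and neither kept its call with an estimated correlation.

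NIK depletion was then set against the same control, which asks what differs when NIK is targeted. DUSP6 stood 1.61-fold higher with the NIK shRNA as well, at 8.17 ± 0.019 (SD, n = 3) against 7.49 ± 0.18 (SD, n = 3) in control. That was a log2 difference of 0.68 on its brightest probe set, against 0.38 ± 0.11 (SE) on the mean over its probe sets. ERRFI1 stood 1.32-fold higher. DVL1, a transducer of Wnt signals, stood 1.73-fold higher on its brightest probe set, but 13 of its 22 probe sets were lower and the mean over them differed by −0.05. CRABP2, a retinoic acid-binding protein, differed by 0.43 ± 0.11 (SE) and ALOX5, the 5-lipoxygenase, by 0.40 ± 0.10 (SE). The lower genes with the smallest p were SLC6A5, a glycine transporter, at −1.62 ± 0.29 (SE) with 13 of 17 probe sets lower, and CD48 at −0.68 ± 0.14 (SE) with 7 of 9 lower. GAB2, an adaptor of receptor tyrosine kinases, differed by −0.64 ± 0.14 (SE) with 8 of 11 lower, and BRSK2, a kinase, by −0.49 ± 0.11 (SE) with 17 of 28 lower. TMEM51 differed by −0.74 ± 0.13 (SE) on its brightest probe set while 7 of its 8 probe sets were higher and their mean differed by 0.11. All 10 of these genes had a limma adjusted p of 0.787, and none passed.

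NFKB2 and BIRC3 did not pass with NIK depletion either. NFKB2 differed by −0.09 ± 0.16 (SE, 95% interval −0.46 to 0.29) and BIRC3 by −0.11 ± 0.15 (SE, 95% interval −0.47 to 0.24), with limma adjusted p of 0.928 and 0.902. Both signs turned on the mean over probe sets, to 0.02 for NFKB2 and 0.28 for BIRC3. Noncanonical components were lower in 7 of 8 (median −0.10, camera adjusted p 0.657), among them CHUK at −0.16 ± 0.10 (SE), TNFRSF1B at −0.23 ± 0.18 (SE) and LTBR at −0.12 ± 0.14 (SE). On the mean over probe sets the direction of this list turned, to a median of 0.02, and CHUK turned to 0.15. Canonical components were lower in 4 of 4 (median −0.10, camera adjusted p 0.733), with ZC3H12A at −0.20 ± 0.15 (SE) and at 0.08 on the mean over probe sets, where the list's direction also turned (median 0.07). The 3 chemokines and cytokines were lower (median −0.21, camera adjusted p 0.657), with CXCL12 at −0.22 ± 0.14 (SE), IL23A at −0.21 ± 0.18 (SE) and CSF1 at −0.11 ± 0.12 (SE). IL23A and CSF1 lay at 0.02 and 0.03 on the mean over probe sets, and the median of this list turned to 0.02.

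No gene list was called in this comparison. The immediate early genes came nearest, with 7 of 10 members higher and a median of 0.19 (camera adjusted p 0.0521, and adjusted p = 0.567 with an estimated correlation). DUSP6 passed when adjusted over the list alone. ATF3, a stress-induced transcription factor, differed by 0.48 ± 0.23 (SE) and PHLDA1 by −0.20 ± 0.12 (SE). Leaving out control 1, control 3, NIK overexpression 1 or NIK overexpression 3 brought the number of called lists from 0 to 1 or 2, the immediate early genes in each case and the small nucleolar RNAs as well without control 3. Small nucleolar RNAs were higher in 7 of 11 (median 0.09, camera adjusted p 0.121), with SNORD44 at 0.35 ± 0.12 (SE), SNORA1 at 0.33 ± 0.14 (SE) and SNORD14E at −0.17 ± 0.095 (SE). The other 19 lists had camera adjusted p from 0.657 to 0.997 and medians from −0.24 (endothelial markers) to 0.14 (fibroblast markers). On the mean over probe sets these 2 medians were −0.12 and −0.02. The signs of median, mean and camera's direction differed in 6 of the 19 lists. By limma 0 genes were called, with 285 (6.05%) at an unadjusted p under 0.05 (90 higher, 195 lower). Evenly spread p-values would give 235.65, while 3.35% of unchanged genes reached such a p in the simulated data. With the array contrast as a covariate the number on the brightest probe sets was 97. That contrast averaged 5.27 with NIK shRNA and 5.17 in control, so the number was not separated from it. Arrays did not overlap for 17.5% of genes against 10% by chance, a share from which the array contrast was not removed. Limma also called 0 on the mean over probe sets, with 572 at an unadjusted p under 0.05 and 224 with the array contrast as a covariate. With trend and robust it called 0, with 434.

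NIK overexpression against NIK depletion set the 2 manipulated arms side by side. INHBE stood 1.83-fold higher with NIK overexpression on its brightest probe set, at 8.98 ± 0.099 (SD, n = 3) against 8.11 ± 0.14 (SD, n = 3). On the mean over its probe sets the levels lay closer, at 7.25 ± 0.11 (SD, n = 3) against 6.83 ± 0.19 (SD, n = 3). TCN1 stood 1.65-fold higher on its brightest probe set. On the brightest probe sets limma's adjusted p was 0.326 for INHBE (0.87 ± 0.12 SE) and 0.9997 for TCN1 (0.72 ± 0.14 SE). TCN1 was the 1 gene called on the mean over probe sets, with a log2 difference of 1.11 ± 0.13 (SE, limma adjusted p 0.0208) and 10 of 10 probe sets higher. Leaving out control 1, NIK shRNA 2, NIK shRNA 3 or any 1 of the 3 NIK overexpression arrays ended that call, at adjusted p from 0.0652 to 0.208, and the difference itself stayed between 1.07 and 1.14 over all 9 single-array omissions. The other genes with the smallest p on the higher side were SLC6A5 (1.31 ± 0.29 SE), KRT7, a simple-epithelial keratin (0.54 ± 0.13 SE), and ITGA8, an integrin chain (1.19 ± 0.28 SE, with 19 of 30 probe sets lower and a mean of −0.12). On the lower side were MSTO1 (−0.49 ± 0.11 SE), DVL1 (−0.56 ± 0.15 SE), PDGFD (−0.66 ± 0.18 SE), SHCBP1L (−0.44 ± 0.13 SE) and UBQLNL (−0.60 ± 0.17 SE). DVL1 and PDGFD turned sign on the mean over their probe sets, to 0.08 and 0.0038. None of these genes passed limma's test.

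BIRC3 stood 1.44-fold higher with NIK overexpression than with NIK depletion (log2 difference 0.53 ± 0.15 SE, 95% interval 0.17 to 0.88), with all 10 probe sets higher. It passed when adjusted over the list alone in the canonical NF-kB list and in the apoptosis list (4 of 5 members higher, median 0.05, camera adjusted p 0.211), but neither in the noncanonical list nor over all genes (limma adjusted p 0.9997). The mean over its probe sets differed by 0.37 ± 0.16 (SE, limma adjusted p 0.807). NFKB2 differed by 0.23 ± 0.16 (SE, 95% interval −0.14 to 0.60). Noncanonical components were higher in 6 of 8 (median 0.13, camera adjusted p 0.135), with CHUK at 0.27 ± 0.10 (SE) on its brightest probe set and −0.06 on the mean, where the list median was 0.00084. Canonical components were higher in 3 of 4 (median 0.16, camera adjusted p 0.213), with RELA at −0.08 ± 0.11 (SE). The chemokines and cytokines IL23A (0.15 ± 0.18 SE), CSF1 (0.01 ± 0.12 SE) and CXCL12 (0.0069 ± 0.14 SE) had a median of 0.01 and a camera adjusted p of 0.804, and all 3 turned sign on the mean over probe sets.

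The cell cycle list was the 1 list called: all 4 measured members were lower with NIK overexpression than with NIK depletion, with a median of −0.17 (camera adjusted p 0.0199, and adjusted p = 0.410 with an estimated correlation). CDC20 differed by −0.37 ± 0.14 (SE), the proliferation marker MKI67 by −0.17 ± 0.093 (SE) and CENPF by −0.17 ± 0.12 (SE), and 0 members passed when adjusted over the list alone. CDC20 differed by only −0.03 ± 0.11 (SE) on the mean over its probe sets, while MKI67 and CENPF lay at −0.22 and −0.25 there. The call was lost without NIK shRNA 2, NIK shRNA 3, NIK overexpression 2 or NIK overexpression 3, at camera adjusted p from 0.0644 to 0.146. DNA replication genes were lower in 3 of 3 (median −0.13, camera adjusted p 0.150): RFC5 by −0.14 ± 0.13 (SE), RRM1 by −0.13 ± 0.13 (SE) and MCM10 by −0.10 ± 0.10 (SE). Basal and myoepithelial markers were lower in 6 of 8 (median −0.18, camera adjusted p 0.0851), with KRT6B at −0.39 ± 0.18 (SE), ACTA2 at −0.26 ± 0.15 (SE) and TAGLN at −0.27 ± 0.17 (SE). On the mean over probe sets the list's median was −0.11, with these 3 genes at −0.22, −0.13 and −0.10. Genes of epithelial-mesenchymal transition were higher in 6 of 6 (median 0.21, camera adjusted p 0.150), with VIM at 0.37 ± 0.21 (SE), MMP3 at 0.34 ± 0.21 (SE) and ZEB1 at 0.21 ± 0.18 (SE). Over all probe sets that median was 0.04, with VIM at 0.0052, ZEB1 at 0.01 and MMP3 at 0.29. Glycolysis and hypoxia genes were higher in 7 of 10 (median 0.12, camera adjusted p 0.150), with PFKFB3 at 0.35 ± 0.11 (SE), BNIP3 at 0.20 ± 0.11 (SE) and MXI1 at 0.22 ± 0.13 (SE), at 0.08, 0.09 and −0.04 on the mean over probe sets. Small nucleolar RNAs were lower in 7 of 11 (median −0.05, camera adjusted p 0.150), with SNORD14E at −0.23 ± 0.095 (SE), SNORA1 at −0.23 ± 0.14 (SE) and SNORD28 at −0.17 ± 0.11 (SE). The other 15 lists had camera adjusted p from 0.211 to 0.813, and signs differed within the stemness and Notch lists. By limma 0 genes were called on the brightest probe sets, with 144 (3.06%) at an unadjusted p under 0.05 (95 higher, 49 lower). Evenly spread p-values would give 235.65, while 3.10% of unchanged genes reached such a p in the simulated data. The number was 276 on the mean over probe sets and 245 with trend and robust. With the array contrast as a covariate it was 142 on the brightest probe sets and 309 on the mean over probe sets. Arrays did not overlap for 10.1% of genes against 10% by chance.

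A limma F-test for any difference among the 3 groups called 0 of 4713 genes on the brightest probe sets (smallest adjusted p 0.207, 214 at an unadjusted p under 0.05). On the mean over probe sets it called 1, TCN1 (limma adjusted p 0.0163, 533 genes at an unadjusted p under 0.05).

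Overexpression and depletion were then compared with each other through their differences from control. Across 4713 genes, which are not independent replicates, the 2 log2 differences correlated with Pearson's r of 0.615 and Spearman's rho of 0.612. Among the named genes DUSP6, TXNIP and ERRFI1 stood higher in both arms. Unchanged groups set against the same 3 control arrays gave a mean r of 0.444 in 100 simulated draws, with a highest r of 0.873. The covariance was 0.0245 against a simulated mean of 0.0137, and 9 of the 100 draws reached the observed covariance. The 3 control arrays cannot be split into parts of 2 arrays each, so the excess was not separated from the shared controls. The array contrast averaged 5.24 with NIK overexpression and 5.27 with NIK shRNA, against 5.17 in control. That contrast was not removed from these values, so the relation was not separated from it either.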

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

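The tests of explanations in this part were chosen after the results were seen. Probe sets that open the table and carry no gene symbol, 4203 in number and outside the comparisons above, had a higher mean with NIK shRNA (8.20 ± 0.035 SD) than in control (8.07 ± 0.054 SD), a difference of 0.123 with all 3 NIK shRNA arrays above all 3 control arrays. The two-sided exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. NIK overexpression differed from control by 0.026 there (exact permutation p 0.5) and from NIK shRNA by −0.097, without overlap of arrays (exact permutation p 0.1), and what these probe sets measure was not given by the files used here. The array contrast was not removed from these differences, and its part in them was not tested. It averaged 5.27 with NIK shRNA, 5.24 with NIK overexpression and 5.17 in control. Control 2 was lowest on both measures (8.01 and 5.12) and NIK shRNA 3 was highest on both (8.23 and 5.33).

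TCN1 stood higher with NIK overexpression on the mean over its probe sets. A single aberrant probe set was argued against, since 10 of 10 probe sets were higher. The array-wide contrast between bright and dim genes, entered as a covariate, changed the difference from control from 1.17 ± 0.13 to 1.03 ± 0.13 (SE) and that from NIK shRNA from 1.11 ± 0.13 to 1.17 ± 0.12 (SE). Its lower 95% bounds of 0.74 and 0.91 stayed above 0.58 and 0.55, each 50% of the uncorrected difference, so the contrast is argued against as the whole cause. The call against control ended (limma adjusted p 0.0730), with a smaller difference at the same SE and 1 residual degree of freedom fewer; their shares in the loss were not separated. An effect of the vector backbone may remain and cannot be told apart from one of NIK, since 0 arrays carried the empty expression vector, so NIK overexpression stays an open biological hypothesis.

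The immediate early genes stood higher with NIK overexpression than in control. The array contrast as the whole cause was argued against at the preset correlation only, since with it as a covariate the list kept a median of 0.18 and its call (camera adjusted p 0.0187). With an estimated correlation the list was called neither without the covariate (adjusted p = 0.178) nor with it (adjusted p = 0.631). A low level of these genes in the control arrays is a candidate explanation: NIK shRNA against control had a median of 0.19, at least as large as the 0.17 of NIK overexpression. That value did not pass its own test (camera adjusted p 0.0521, and adjusted p = 0.567 with an estimated correlation). A further difference between the 2 arms is not ruled out: the list had a camera adjusted p of 0.211 there, but was called as higher with NIK overexpression on the mean over probe sets with the array contrast as covariate (camera adjusted p 0.0331, and adjusted p = 0.377 with an estimated correlation). An effect of NIK on the list stays open.

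The 2 comparisons against control moved together across genes. Shared control arrays may account for this, since 9 of 100 simulated draws of unchanged groups reached the observed covariance. The array contrast, higher on average in both arms than in control, was not removed from that covariance. No biological explanation was tested for this relation.

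Other splits of the arrays were counted for each result of the fit. With 10 splits of 6 arrays a share under 0.05 is out of reach. Where the real split called 0, every split is as large by definition, so that share carries no information on chance. For NIK overexpression against control, 0 genes were called in the real split and at most 0 in the others (10 of 10 as large), and on the mean over probe sets 3 against at most 0 (1 of 10). Called lists numbered 1 against at most 2 (2 of 10), and on the mean 3 against at most 5 (2 of 10). For NIK shRNA against control 0 genes were called by either summary in the real split and at most 0 in the others, and 0 lists against at most 1, or 3 on the mean (10 of 10 as large in each). For NIK overexpression against NIK shRNA, 0 genes against at most 0 (10 of 10), 1 on the mean against at most 0 (1 of 10), 1 list against at most 0 (1 of 10) and 4 lists on the mean against at most 1 (1 of 10). For the F-test, 100 splits of the 9 arrays were drawn: the real split called 0 genes and the others at most 0 (100 as large). On the mean over probe sets the real split called 1, and the highest other split also called 1 (7 of 100 as large), so chance cannot be excluded for that count.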

How the results depend on the processing

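The mean over probe sets, the array contrast and the omission of both end arrays of the first principal component were chosen after the results were seen. Where a value below differs from the one reported above, the cause was not tested. In the simulated data, 2.48% to 3.35% of unchanged genes reached an unadjusted p under 0.05 by limma on the brightest probe sets. That is fewer than evenly spread p-values give, so this fit was conservative there, a limit on the calls of 0.

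The number of genes called by limma for NIK overexpression against control, 0 above, became 3 with dim probe sets left out (INHBE, DUSP6 and PCDH15), 6 with trend and robust in eBayes (the same 3 with TXNIP, VASH2 and ERRFI1) and 3 on the mean over probe sets. The number against NIK shRNA went from 0 to 1 with dim probe sets left out (INHBE) and 1 on the mean over probe sets (TCN1). The F-test went from 0 to 1 with dim probe sets left out, 1 with trend and robust and 1 on the mean over probe sets. For NIK shRNA against control it stayed at 0 in these settings and in each single omission on the brightest probe sets. With the replicate number as a replicate block, 0 genes were called in each of the 3 comparisons; residuals of same-numbered arrays correlated between −0.103 and 0.0748, so the arrays were not treated as paired.

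Lists called by camera for NIK overexpression against control, 1 above, numbered 3 on the mean over probe sets and 0 with an estimated correlation, and 1 to 4 when single arrays were left out (4 without control 3, 2 without NIK overexpression 1). The immediate early genes kept their call at the preset correlation with the replicate block, with dim probe sets left out, with the array contrast, without both end arrays and without each array, with camera adjusted p from 0.000763 to 0.0204 on the brightest probe sets; their median lay between 0.14 and 0.28 under single omissions. Camera adjusted p for them on the mean over probe sets ran from 0.000279 (without control 3) to 0.0443 (without both end arrays). For NIK shRNA against control, 0 above, single omissions gave 0 to 2. The number for NIK overexpression against NIK shRNA, 1 above, was 4 on the mean over probe sets, 0 without both end arrays, 0 with an estimated correlation and 0 with fry, and 0 to 2 when single arrays were left out (2 without control 2). The cell cycle list lost its call without both end arrays, and its camera adjusted p lay between 0.00411 and 0.146 when single arrays were left out (0.146 without NIK shRNA 3).

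On the mean over probe sets, the 3 genes called for NIK overexpression against control became 1 with the replicate block (TCN1), 0 with the array contrast and 0 without both end arrays, and 0 to 3 when single arrays were left out. The difference of TCN1 lay between 1.01 and 1.33 in all of these. The 1 gene called against NIK shRNA became 0 to 4 under single omissions (4 without NIK shRNA 1), the 1 gene of the F-test 0 to 3, and the 0 genes for NIK shRNA against control 0 to 2 (2 without NIK shRNA 1). Lists called on that mean for NIK overexpression against control, 3 above, became 2 with the array contrast (immediate early genes, and glycolysis and hypoxia, with 0 at an estimated correlation as well). They became 1 without both end arrays and 3 to 5 under single omissions (5 without control 3). Without control 3 the added lists, both higher, were canonical NF-kB (4 members, camera adjusted p 0.0177) and glycolysis and hypoxia (camera adjusted p 0.0415), at the preset correlation. The 4 lists against NIK shRNA became 5 with the array contrast, which added the immediate early genes (0 with an estimated correlation as well). They became 0 to 4 under single omissions, with 0 without NIK shRNA 3 or NIK overexpression 3. The 0 lists of NIK shRNA against control became 0 to 2 (2 without control 3). Pearson's r between the 2 comparisons against control lay between 0.458 and 0.717 under single omissions.

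Several log2 differences turned sign on the mean over probe sets. For NIK shRNA against control these were DVL1 (−0.054), TMEM51 (0.11), NFKB2 (0.017), BIRC3 (0.28), ZC3H12A (0.080), IL23A (0.022), CSF1 (0.026) and CHUK (0.15). For NIK overexpression against NIK shRNA they were ITGA8 (−0.12), DVL1 (0.081), PDGFD (0.0038), IL23A (−0.052), CSF1 (−0.058), CXCL12 (−0.15), MXI1 (−0.043) and CHUK (−0.056), and for NIK overexpression against control HSPA6 (−0.029).

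With the array contrast as a covariate, CXCL12 turned to −0.063 for NIK overexpression against NIK shRNA, and for NIK shRNA against control LTBR turned to 0.096 and TCN1 on the mean over probe sets to −0.15. Without both end arrays CSF1 turned to −0.0047 for NIK overexpression against NIK shRNA and TCN1 on the mean to −0.10 for NIK shRNA against control.

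Leaving out single arrays gave ranges that crossed 0 for small differences. For NIK shRNA against control these were NFKB2 (−0.21 to 0.066, above 0 without NIK shRNA 2), BIRC3 (−0.19 to 0.039, above 0 without NIK shRNA 3), LTBR (−0.19 to 0.00682, above 0 without NIK shRNA 3) and TCN1 on the mean (−0.10 to 0.22, below 0 without control 2). With NIK overexpression against control they were IL23A (−0.14 to 0.054, above 0 without control 3 or NIK overexpression 2) and HSPA6 (−0.00230 to 0.34, below 0 without control 3). Between the 2 manipulated arms they were CSF1 (−0.028 to 0.076, below 0 without NIK shRNA 1, NIK shRNA 3 or NIK overexpression 2) and CXCL12 (−0.090 to 0.14, below 0 without NIK shRNA 2, NIK overexpression 1 or NIK overexpression 3).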

Other observations

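On the mean over probe sets, a summary chosen after the data were seen, further gene lists passed camera with the preset correlation. With NIK overexpression against control these were p53 targets (9 measured, median 0.16, camera adjusted p 0.0134) and targets of the unfolded protein response and ATF4 (6 measured, median 0.13, camera adjusted p 0.0134), both higher, beside the immediate early genes (median 0.23, camera adjusted p 0.00189). With NIK overexpression against NIK shRNA, interferon-stimulated genes (13 measured, median −0.07, camera adjusted p 0.00817) and DNA replication genes (3 measured, median −0.11, camera adjusted p 0.0483) were lower beside the cell cycle genes (median −0.22, camera adjusted p 0.00817), and targets of the unfolded protein response and ATF4 were higher (median 0.17, camera adjusted p 0.0483). For NIK overexpression against control the p53 and ATF4 lists lost their calls with the array contrast as covariate and without both end arrays of the first principal component. Against NIK shRNA the ATF4 list lost its call with the replicate block, without both end arrays, and without control 1, control 2, NIK shRNA 1, NIK shRNA 3, NIK overexpression 2 or NIK overexpression 3. The DNA replication list lost its call without control 1, NIK shRNA 1, NIK shRNA 3, NIK overexpression 1 or NIK overexpression 3, and the cell cycle and interferon lists lost theirs without NIK shRNA 3 or NIK overexpression 3. None of these lists was called with an estimated correlation, where adjusted p was 0.428 for the first comparison's lists and 0.512 for the second's.

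BIRC3 differed between its probe sets and its brightest one. On the mean over its 10 probe sets it stood at 7.39 ± 0.31 (SD, n = 3) with NIK overexpression, 7.02 ± 0.17 (SD, n = 3) with NIK shRNA and 6.74 ± 0.22 (SD, n = 3) in control, so that both manipulated arms had higher means than control. Of its probe sets 10 were higher with NIK overexpression and 8 with NIK shRNA. Limma's adjusted p on that mean was 0.172 for NIK overexpression and 0.477 for NIK shRNA, neither past the threshold. The BIRC3 difference between NIK overexpression and control lay between 0.53 (without control 2) and 0.83 (without NIK overexpression 1) when single arrays were left out.

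TXNIP, which encodes an inhibitor of thioredoxin, was ordered alike on all its probe sets: 10 of 10 were higher than control with NIK overexpression and 10 of 10 with NIK shRNA, with median differences of 0.66 and 0.32. These probe sets were read on the same arrays and are not independent. On their mean, the call for NIK overexpression was lost with the replicate block, with the array contrast and without both end arrays. For NIK shRNA against control limma called 0 genes on the mean over probe sets.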
